A study of Homo sapiens with 19 samples.

How the data were processed

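RNA was measured on 19 Affymetrix arrays: 8 arrays of one design (12600 probe sets) for purified blood cell RNA treated with cell extract, and 11 arrays of another design (22283 probe sets) for 4 samples of thawed blood cells and 7 samples of NB4 cells. Targets were made from about 8 ug of total RNA per array with standard Affymetrix procedures, per the labels. The deposited values are linear intensities, 1 per probe set. How the authors summarised the probe cells of a probe set into that intensity is not given in the sources used here. The 2% trimmed means of the deposited intensities lay within 1.71% of their mean on the 8 extract arrays (146.8 to 151.5), so these arrays were taken as already scaled to one another. On the other 11 arrays the trimmed means ranged from 532.5 to 682.4 and deviated by up to 14.9%, so those arrays were taken as not scaled across the 2 experiments. No array was an identical copy of another (0 such arrays).

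The following choices were made before the data were examined: the groups, the tests, the filters, 29 gene lists, the rule for naming genes, and the alternatives. Arrays whose trimmed means lay within 5% of their mean were used as deposited, and the others were quantile normalized within each comparison. Intensities under 20 were set to 20 and converted to log2. Affymetrix control probe sets were left out of the gene tests (67 on the first design and 68 on the second). Only probe sets whose mean log2 intensity reached the median probe set over the arrays of a comparison were tested, which left 6267 and 11108. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 4 extract amounts shared one estimate of the spread, and a second fit regressed the log2 intensity on the degradation factor in the labels. In NB4 cells the 3 valproate times were taken as replicates of the treatment against 4 mock arrays, so their spread includes any change with time. The 24 h valproate array was also set against the 3 mock arrays of 24 h, with the lone treated array assumed to vary like them. The 8 h pair has 1 array per arm and was only counted beyond 2-fold. The labels call the 3 mock arrays of 24 h replicates run in parallel and do not otherwise say whether arrays of a group came from separate cultures, so the p-values measure the spread between these samples.

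Genes were named through the platform annotation, with symbols updated through Entrez identifiers in the RefSeq annotation of GRCh38.p14, which was used only for names. On the first design 10937 probe sets carried 1 gene, 545 several and 1118 none, and on the second 19071 carried 1 gene, 1043 several and 2169 none. No gene was named from a probe set with several. In each main comparison the 8 largest rises and 8 largest falls among probe sets past the threshold were named, if the groups did not overlap, with 1 probe set per gene. Where none passed, the 5 smallest p-values were named as not passing. Up to 4 members of each gene list were eligible, those past the threshold first. Each list was tested with limma's camera at a preset correlation of 0.01, with 1 probe set per gene (the brightest) and at least 5 members, and again with an estimated correlation.

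RNA integrity was measured as the log2 difference of the 3′ and 5′ control probe sets of ACTB and GAPDH, and also of TFRC. The adjustment for multiple tests also covers a further control, whose result is not reported here. These ratios were tested with exact two-sided permutation tests in scipy 1.17.1 (Python 3.11.15, numpy 2.4.6), whose two-sided p doubles the smaller tail. Counting regroupings by absolute size instead gives smaller values for groups of unequal size, and such a value is given beside the NB4 result. Figures were drawn with matplotlib 3.10.9.

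The letters A and B in the titles of the extract samples were checked for pairing. Deviations from the group means correlated within a letter in each of the 6 pairs of amounts (r 0.618 to 0.799 across probe sets), so the letters pair the arrays, and counts with the letter as a block are given where they change a call or move a count by more than 1.5 times. The pairing comes from this correlation, not from a statement in the labels.

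Each fit was tested on simulated arrays with the measured means and spreads, 10 draws with 200 changed probe sets each. For 100 ng against 0 ng (6267 probe sets) the fit recovered 67.2% of 1.5-fold, 82.4% of 2-fold and 84.2% of 4-fold changes. For the thawed cells (11108 probe sets) it recovered 0.2%, 25.8% and 70.6% of these. For valproate against mock (11108 probe sets) it recovered 63.8%, 83.2% and 78.8%. Part of the simulated 4-fold decreases fell under the intensity filter, 15%, 26.6% and 21% of the 4-fold changes in these 3 comparisons. For 24 h alone, 9.37% of the simulated calls were false, above the nominal 5%. The share was also above it for the thawed cells (7.65%) and for 50 ng (5.97%), and was 4.29% to 5.04% in the other fits. The gene set test found the shifted list in 10 of 10 draws, and 2 unshifted lists passed over those draws. The simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.891 for the mitosis genes in NB4 cells. The simulation therefore does not test lists whose members vary together.

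The alternatives were another normalization, floors of 1 and 100, no filter and a stricter filter, probe sets of single transcripts only, leaving out each array, the letters as a block, other sets of arrays in a fit, and an estimated correlation in the list tests. Folds are relative to the overall brightness of the arrays, and were set against the hybridization spikes after the results were seen; the amount of spike per array is not given in the sources used here. The number of arrays limits the precision. Genes whose level could describe a person were left out of the named genes.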

Results

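Gene expression was measured on 19 arrays in 3 experiments on RNA breakdown and cell death. In the first, purified RNA of peripheral blood mononuclear cells was incubated for 10 min without extract or with 25, 50 or 100 ng of an extract of the same cells, a source of RNases, on 2 arrays per amount, A and B. The labels give each sample a degradation factor, which was 6 and 3 without extract, 13 and 16 at 25 ng, 21 and 19 at 50 ng, and 40 and 44 at 100 ng. They name 1 donor for the 0, 25 and 50 ng samples and 4 donors for the 100 ng samples, so that step in extract is also a change of donors. In the second, frozen blood mononuclear cells were thawed and left at room temperature for 0 or 5 min, with 2 arrays each, h and n. In the third, NB4 cells, an acute promyelocytic leukaemia line, received 5 mM valproate to induce apoptosis for 8, 24 or 32 h on 1 array each. Mock-treated NB4 cells were measured on 1 array at 8 h and 3 arrays at 24 h. Valproate is an antiepileptic drug that inhibits histone deacetylases. Median deposited intensities per array were 108.8 to 111.9 on the extract arrays, 311.6 to 336 on the thawed-cell arrays and 370.5 to 393.9 on the NB4 arrays.

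The extract experiment addresses how RNA breakdown alters a measured profile. The 5′ end of the actin transcript lost signal relative to its 3′ end with increasing extract. The log2 ratio of the 3′ to the 5′ probe set of ACTB, cytoskeletal actin, was 0.35 ± 0.065 (SD, n = 2) without extract, 1.07 ± 0.0035 at 25 ng, 1.57 ± 0.015 at 50 ng and 2.36 ± 0.15 at 100 ng. The intensity of the 5′ probe set of ACTB was 2780 ± 289 without extract and 797 ± 97.2 at 100 ng, against 3532 ± 209 and 4066 ± 74.2 for the 3′ probe set. The ratio of GAPDH, a glycolytic enzyme, was 0.94 ± 0.12 without extract and 2.26 ± 0.083 at 100 ng. Over the 8 arrays the ACTB ratio correlated with the degradation factor (r = 0.963, exact permutation p = 0.000546, adjusted 0.00109; Spearman's coefficient 0.952, exact permutation p = 0.00114, adjusted 0.00228). The GAPDH ratio did so too (r = 0.977, exact permutation p = 0.000248, adjusted 0.000992; Spearman's coefficient 0.976, exact permutation p = 0.000397, adjusted 0.00159). Without the 2 arrays farthest from the median factor, both of 100 ng, r was 0.981 for ACTB (exact permutation p = 0.00833) and 0.996 for GAPDH (exact permutation p = 0.00278). Within A and within B each of these ratios increased in 3 of 3 steps of the factor, and 4 arrays per letter are too few for a correlation. For TFRC, the transferrin receptor, r was -0.631 (exact permutation p = 0.0612, adjusted 0.0816; Spearman's coefficient -0.548, exact permutation p = 0.171), but its probe sets were dim (100.4 at the 3′ and 105.5 at the 5′ end without extract) and say little about breakage. The adjustment is over a family of 4 tests.

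**Figure D1:**
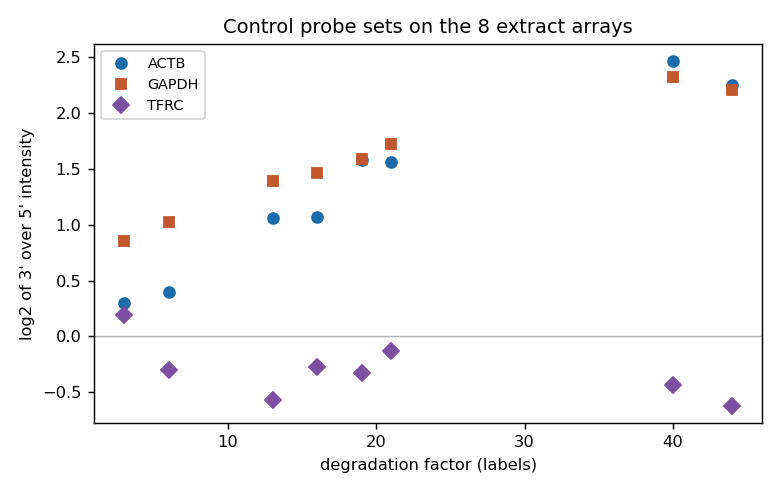
Log2 ratio of the 3′ to the 5′ control probe set of 3 genes (vertical axis) against the degradation factor in the labels (horizontal axis), 1 point per array and gene on the 8 extract arrays. The ratio was 0.35 on average without extract and 2.36 at 100 ng for ACTB.

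At 100 ng, DUSP1, a phosphatase that switches off MAP kinases, fell by 1.97 on the log2 scale (SE 0.16, adjusted p = 0.00324), from 647 ± 136 (SD, n = 2) to 163 ± 5.46. PTPRC, the CD45 phosphatase of leukocytes, fell from 553.5 ± 17 to 196 ± 0.0636 (adjusted p = 0.00111), and GNAS, a G protein subunit, from 1157 ± 10.3 to 396 ± 32 (adjusted p = 0.0034). ITM2B (log2 fold -1.57), ARHGDIB (-1.41), FOS, an immediate early transcription factor (-1.30), and YWHAZ, a 14-3-3 protein (-1.29), fell as well. 1 probe set of VCAN, a matrix proteoglycan, fell by 1.74 on the log2 scale, but both other probe sets of VCAN had the opposite sign, as did 1 of 2 others of FOS. Among rises, CD180, a receptor of B cells, went from 73.4 ± 0.11 to 186 ± 38.7 (log2 fold 1.33, SE 0.15, adjusted p = 0.00615), and ATP5F1B, the beta subunit of ATP synthase, from 119 ± 1.04 to 264 ± 27.7 (1.15, adjusted p = 0.00287). POLR1F, a subunit of RNA polymerase I (1.09), NME1, a nucleoside diphosphate kinase (1.04), CCL19, a chemokine (0.99), DLX4, a homeobox factor (0.97), POLR3G (0.95) and FGFR1, a growth factor receptor (0.93), rose as well, with 2 of 3 other probe sets of FGFR1 opposite in sign. The means of these 16 genes moved one way through every amount, DUSP1 being at 376 ± 41.1 (SD, n = 2) with 25 ng and 288 ± 31.8 with 50 ng. Without the 0 ng B array the calls of CD180 (adjusted p = 0.0626), DLX4 (0.0588), POLR1F (0.104), CCL19 (0.0575), NME1 (0.0588), POLR3G (0.0956) and YWHAZ (0.0539) were lost. CD180, DLX4 and POLR1F were lost without the 0 ng A array too, with adjusted p-values of at most 0.0723. Without extract CD180 (73.4), POLR1F (80) and POLR3G (76.9) were dimmer than the TFRC probe sets called dim above, so their rises need the same caution.

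**Figure D2:**
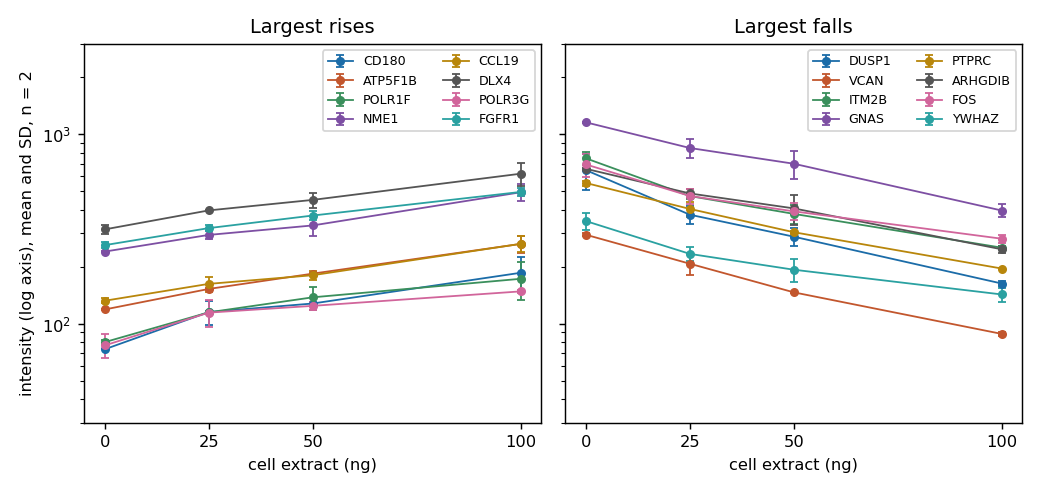
Intensity of the 8 genes with the largest rises (left) and the 8 with the largest falls (right) at 100 ng, against the amount of extract in ng, as means with SD bars of 2 arrays on a log axis. DUSP1 goes from 647 to 163 and CD180 from 73.4 to 186, with intermediate values at 25 and 50 ng.

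In all, 544 of 6267 probe sets changed at 100 ng (limma), 278 up and 266 down, and 30 of the 544 changed by 2-fold or more, 8 up and 22 down. These directions are relative to the overall brightness of the arrays. The median of the 9 hybridization spike probe sets was higher by 1.39 on the log2 scale at 100 ng, and 278 of the 278 rises, the 8 named above among them, were smaller than that and would be falls relative to the spikes. The median log2 fold of the rising probe sets was 0.22 at 25 ng, 0.32 at 50 ng and 0.50 at 100 ng, and that of the falling ones -0.19, -0.27 and -0.50. The values moved in one direction through every step for 239 of the 278 and 219 of the 266. Both arrays of 100 ng lay on one side of both of 0 ng for 58.9% of probe sets, where chance gives 33.3% for independent arrays, which those paired by letter are not. At 50 ng 6 probe sets changed, 1 up and 5 down, among them VCAN (log2 fold -1.01), ITM2B (-0.98) and PTPRC (-0.86), each with an adjusted p of 0.045. At 25 ng 0 changed (limma, smallest adjusted p = 0.632), with 428 at an unadjusted p below 0.05. Regressed on the degradation factor, 705 probe sets changed, 346 up and 359 down. With the letters A and B as a block the counts were 2289 at 100 ng, 554 at 50 ng, 23 at 25 ng and 1769 for the regression. The 100 ng count fell with any array left out, to 33 without 0 ng B, 74 without 0 ng A, 109 without 100 ng A, 114 without 100 ng B, 351 and 346 without 25 ng A and B, and 323 without either 50 ng array. It was 157 with only the 0 and 100 ng arrays in the fit and 323 among single-transcript probe sets. The regression gave 224 without 0 ng B, 308 without 0 ng A, 286 without 100 ng A and 5 without both 100 ng arrays, and the 50 ng count was 0 or 1 without any 1 array.

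Gene groups, read by the brightest probe set of each gene, moved in both directions at 100 ng. Of 40 tested genes of the nuclear respiratory chain 5 rose and 1 fell (6 and 1 adjusted over the list alone), with ATP5F1D (log2 fold 0.59) and NDUFS5 (0.55) higher and ATP5F1A, the alpha subunit of ATP synthase, lower (-1.02). Of 44 ribosomal protein genes 3 fell, RPLP1 (-0.40), RPL31 (-0.32) and RPL41 (-0.32), and 0 rose (4 fell and 2 rose adjusted over the list alone), and these 3 calls were lost after quantile normalization, which kept their sign (adjusted p = 0.0513, 0.0557 and 0.134). Of 25 proteasome genes PSMB6 (0.60) and PSMD1 (0.38) rose and PSMD8 (-0.42) fell, with the same counts adjusted over the list alone. Of 10 T cell markers ZAP70, a receptor kinase (0.51), CD6 (0.42) and CD3D (0.39) rose (3 rose and 2 fell adjusted over the list alone), although CD3D did not pass after quantile normalization (adjusted p = 0.0557). Of 8 B cell markers CD79B rose (0.43), and of 6 platelet markers NRGN (0.63) and ITGA2B (0.56) rose, with the same counts adjusted over the list alone. Among 15 immediate early genes JUNB rose (0.36) and DUSP1 and DUSP2 (-0.56) fell (the same adjusted over the list alone), although JUNB did not pass after quantile normalization (adjusted p = 0.0601), and FOS did not pass by its brightest probe set (0.15), unlike the one above. Among 7 heat shock genes HSPE1 fell (-0.47), with 1 rise and 2 falls adjusted over the list alone. None of the 12 monocyte, 10 NK and cytotoxic, 6 granulocyte and 5 erythroid markers passed limma's threshold by that probe set, and none did adjusted over the list alone, although another probe set of VCAN, in the monocyte list, fell (above). With the letters A and B as a block, 15 respiratory chain genes rose and 7 fell, 2 ribosomal protein genes rose and 8 fell, 10 proteasome genes rose and 2 fell, 4 immediate early genes rose and 4 fell, and 2 heat shock genes rose and 2 fell. In that fit 4 T cell markers rose and 3 fell, 3 B cell markers rose and 1 fell, 3 monocyte markers rose and 1 fell, 3 NK and cytotoxic and 2 granulocyte markers rose, and 2 erythroid markers fell. No list of the 27 tested passed camera (adjusted p = 0.74 to 0.988), and none with the letters as a block or an estimated correlation. Of the 18 list members named here 18 calls were lost without 0 ng B, 17 without 0 ng A, 17 without 100 ng A and 16 without 100 ng B, and 8 or 9 without any other array, with adjusted p-values of up to 0.23. With only the 0 and 100 ng arrays in the fit 15 of the 18 were lost (adjusted p = 0.0512 to 0.117), with no intensity filter 7 (up to 0.0833), and among single-transcript probe sets 3 (up to 0.053).

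In the thawed cells, which test RNA breakdown inside cells, 0 of 11108 probe sets passed between 5 and 0 min (limma, smallest adjusted p = 0.437), with 669 at an unadjusted p below 0.05. The 2 times stood apart for 32.2% of probe sets, where chance gives 33.3% for independent arrays. The thawed arrays may not be independent, since deviations of h and n correlated between the times (r = 0.759). The smallest p-values belonged to MCL1, an anti-apoptotic protein with a short-lived transcript, at 800 ± 138 (SD, n = 2) after 0 min and 161 ± 8.12 after 5 min (log2 fold -2.30, 1 of 4 other probe sets opposite), ENO1, a glycolytic enzyme (-1.54), TMED2 (-1.35, 1 of 2 others opposite), CLC, the Charcot-Leyden crystal protein of eosinophils and basophils (-1.35), and DDX3X, an RNA helicase (-1.13). The log2 ratio of the 3′ to the 5′ probe set was -0.19 ± 0.048 after 0 min and 0.24 ± 0.13 after 5 min for ACTB, and 0.51 ± 0.031 and 1.06 ± 0.042 for GAPDH. Each of these differences had an exact permutation p of 0.333, the smallest that 2 against 2 arrays allow. With a spread estimated from all 11 arrays of the design, 161 probe sets passed, 49 up and 112 down. With h and n as a block 1016 passed. The labels do not state that pairing, as they do not for A and B. The count of 0 therefore holds only for arrays taken as unpaired.

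As a group, the 12 NK and cytotoxic markers were shifted down in the thawed cells after 5 min (camera, adjusted p = 0.000267, median log2 fold -0.30). The call was lost at an adjusted p = 0.856 with an estimated correlation. That estimate was -0.0388, below the preset 0.01, so a higher correlation of the members does not account for the loss. GZMA, a granzyme (-0.51), KLRD1, an NK receptor (-0.44), CTSW (-0.34) and NKG7 (-0.33) had the smallest p-values in it, and none passed alone. The 28 proteasome genes were shifted down (camera, adjusted p = 0.0234, median -0.11), which was lost at an adjusted p = 0.856 with an estimated correlation. Their members pointed apart, with PSMB2 at 0.97, PSMA3 at -0.42 and PSMB7 at -0.32. The other blood cell lists did not pass, with medians of -0.19 (T cells, adjusted p = 0.0884), -0.23 (B cells, 0.316), -0.29 (monocytes, 0.093), -0.086 (platelets, 0.07), -0.021 (granulocytes, 0.332) and 0.011 (erythroid, 0.769). In the monocyte list CTSS (-0.88) and MNDA (-0.62) did not pass. TNFSF10, the death ligand TRAIL (0.74), and CFLAR, an inhibitor of caspase 8 (0.75), did not pass either. For CFLAR and TNFSF10 the values were adjusted p = 0.571 and 0.528. Over each list alone, 1 gene rose among the anti-apoptotic genes, 1 among the death receptor genes and 0 in the NK and proteasome lists. These list results take the arrays as unpaired. With h and n as a block the NK and cytotoxic, monocyte, platelet, B cell and T cell lists passed camera as down. The proteasome list did not pass in that block, and the marker lists did not pass there with an estimated correlation.

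Genes that responded to extract leaned the same way in the thawed cells. Of 194 genes that fell with the degradation factor, 131 (67.5%) had a negative fold after 5 min, against 40.4% of all 3429 genes on both arrays, and of 229 that rose, 174 (76%) had a positive fold. The slope on the factor and the thaw fold correlated across these genes (r = 0.218, Spearman's coefficient 0.206). The same slope had no such relation to the valproate fold in NB4 cells (r = -0.00905, Spearman's coefficient -0.0058, 3321 genes), where 49.4% of 180 falling genes were negative and 46.8% of 216 rising genes positive. Genes are not independent replicates, so these correlations carry no p-value.

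The NB4 experiment asks which transcripts change when valproate drives leukaemic promyelocytes into apoptosis. Transcripts of the promyelocyte granule list fell. MPO, myeloperoxidase, was at 13800 ± 570 (SD, n = 3) in mock cells at 24 h and at 9040, 937 and 478 after 8, 24 and 32 h of valproate (log2 fold of all times -3.07, SE 0.83, adjusted p = 0.0205). PRTN3, proteinase 3, was at 1673 ± 108 in mock cells at 24 h and at 913, 98.7 and 82.8 (-3.12, adjusted p = 0.0106). All 8 tested genes of the promyelocyte granule list fell (8 adjusted over the list alone), among them AZU1, azurocidin (-2.20), and CEBPE, a factor of late granulocyte maturation (-1.86). The list passed camera (adjusted p = 0.00174), and had an adjusted p = 0.624 with an estimated correlation. MPO and PRTN3 were much lower after 24 and 32 h than after 8 h, and this difference over time counts as replicate spread in their calls. The calls of MPO and PRTN3 were lost without the 24 h valproate array (adjusted p = 0.0871 and 0.0508), that of MPO without the mock 24 h replicate 3 array (0.0519), and that of AZU1 without any array but the 8 h valproate one (up to 0.101). CEBPD, a factor of myeloid differentiation, fell from 3013 ± 449 (SD, n = 4) to 249 ± 29.3 (SD, n = 3; log2 fold -3.59, SE 0.14, adjusted p = 1.18e-05) and was already at 241 after 8 h. NFE2, a factor of megakaryocytes and erythroid cells, fell by 2.81 (adjusted p = 2.51e-05).

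Some proliferation genes fell and the cell cycle inhibitor CDKN1A rose. MYC, which drives growth and ribosome production, was at 6256 ± 255 (SD, n = 3) in mock cells at 24 h and at 1716, 1120 and 1253 after 8, 24 and 32 h of valproate (log2 fold -2.17, SE 0.15, adjusted p = 4.16e-05). CDKN1A was at 328 ± 9.25 and at 1241, 2062 and 1952 (2.25, SE 0.20, adjusted p = 0.00015). Of 18 S phase genes 6 fell and 0 rose, among them TYMS, thymidylate synthase (-1.67), and the replication helicase subunits MCM7 (-1.26), MCM2 (-1.23) and MCM5 (-0.83). Of 20 mitosis genes 4 fell, CCNA2 (-0.95), CCNB1 (-0.91), PLK1 (-0.87) and AURKA (-0.80). Of 14 genes of ribosome biogenesis and MYC targets 8 fell and 1 rose, with MYC, CAD, an enzyme of pyrimidine synthesis (-1.54), NOP16 (-1.07) and WDR43 (-0.97) lower. Adjusted over the list alone, 6 S phase, 4 mitosis and 9 ribosome biogenesis genes fell and 1 of the last rose. The 3 lists passed camera as down (adjusted p = 0.00375, 0.0366 and 0.00571). With an estimated correlation they had an adjusted p = 0.692, 0.771 and 0.624. CCNB1 did not pass without any 1 mock array or the 24 h valproate array (adjusted p of up to 0.0746), nor AURKA without any 1 mock array (up to 0.0599), and the mitosis list had an adjusted p = 0.0593 without the 8 h arrays.

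Groups known to respond to deacetylase inhibitors or p53 were higher. All 6 metallothioneins, which bind zinc and copper, rose (6 adjusted over the list alone), MT1E by 0.67, MT1F by 0.49, MT1X by 0.46 and MT1H by 0.40 on the log2 scale, the last 3 by less than the hybridization spikes did (0.60). The probe sets of these 4 are not among those of single transcripts, so their rises may not be separate signals. Of the 6 metallothioneins 3 also stand in another list. Of 11 genes often raised by deacetylase inhibitors 8 rose and 1 fell (the same adjusted over the list alone), with CLU, clusterin (0.89), GLRX, glutaredoxin (0.75), and SAT1, which acetylates polyamines (0.74), beside CDKN1A, and 7 of the 11 also stand in another list. Of 8 p53 targets 7 rose (7 adjusted over the list alone), including SESN1 (0.99), PMAIP1 (0.79) and ZMAT3 (0.54), but the median of the list (0.54) was below the shift of the spikes. The 50 ribosomal protein genes were shifted up by a median of 0.090, with RPLP2 (0.75) and RPS25 (0.25) the 2 that rose and 0 adjusted over the list alone, a median below that shift too. These 4 lists passed camera (adjusted p = 0.00333, 0.00375, 0.00333 and 0.0231), and each had an adjusted p = 0.624 with an estimated correlation. CLU did not pass without the mock 8 h, the mock 24 h replicate 1 or the 24 h valproate array (up to 0.0809), nor PMAIP1 without the last (0.0532). RPLP2 and RPS25 did not pass without any array but the mock 24 h replicate 2 and the 8 h valproate one (up to 0.0893 and 0.143), nor with no intensity filter (0.0532 and 0.0546), nor RPS25 with the deposited scaling, where its sign stayed (adjusted p = 0.199).

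**Figure D3:**
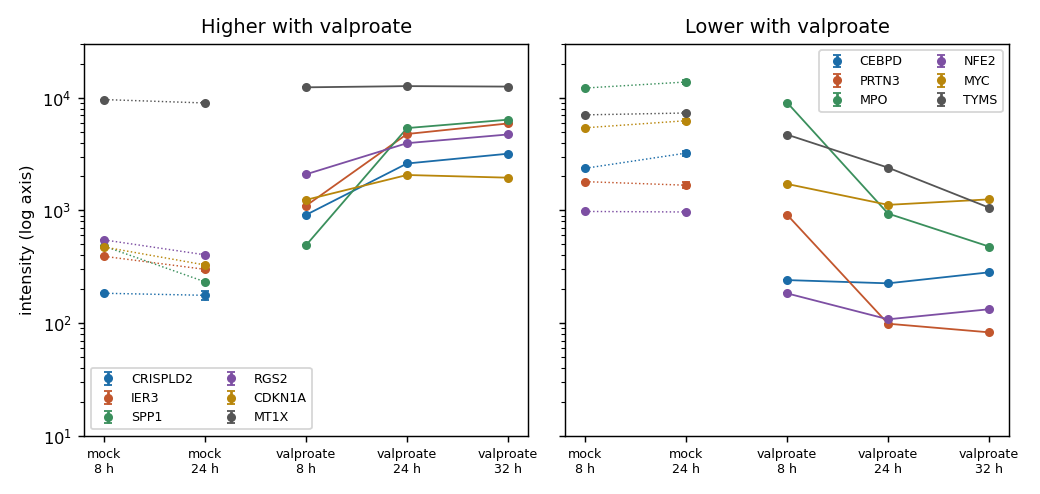
Intensity on a log axis of 6 genes that rose (left) and 6 that fell (right) with valproate, in mock NB4 cells at 8 and 24 h and in cells treated for 8, 24 and 32 h; the mock 24 h points are means of 3 arrays with SD bars and all others are 1 array. MPO goes from 13800 in mock cells at 24 h to 478 after 32 h, and CDKN1A from 328 to 1952.

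Genes of the death machinery moved both ways. Of 5 anti-apoptotic genes BCL2 (-1.34) and CFLAR (-0.55) fell while BIRC2, an inhibitor of apoptosis (0.97), and MCL1 (0.55) rose. Of 8 genes of the mitochondrial pathway 4 rose, including PMAIP1, BAD (0.55) and DIABLO (0.45), and BID fell (-0.94). Of 9 death receptor genes TNFRSF10B, a TRAIL receptor (2.12, SE 0.28, adjusted p = 0.000834), and TRADD (0.44) rose and TNFRSF1A (-0.41) fell. The rises of MCL1, BAD, DIABLO and TRADD were smaller than that of the spikes. The counts were the same adjusted over each list alone, and the lists did not pass camera (adjusted p = 0.851, 0.147 and 0.678). CFLAR was lost without any 1 mock 24 h array or the 8 or 24 h valproate array (up to 0.103), and TRADD without any array but the 8 h valproate one (up to 0.0921), and both with no intensity filter (0.0606 and 0.0574).

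The remaining genes with the largest rises after valproate were CRISPLD2, a secreted protein (log2 fold 3.47, adjusted p = 0.000306), TSPAN13 (3.44), IER3, a stress-induced survival gene (3.30), SPP1, osteopontin (3.21), ICAM1, an adhesion molecule (3.05), RGS2, a regulator of G proteins (2.96), TSC22D1 (2.68) and FUCA1, a lysosomal fucosidase (2.50). SPP1 was at 232 ± 2.53 (SD, n = 3) in mock cells at 24 h, 481 in mock cells at 8 h, and 492, 5379 and 6385 after 8, 24 and 32 h of valproate, and did not pass without the 24 h valproate array (adjusted p = 0.0703). The other large falls were MOK, a kinase (-2.97), YME1L1, a mitochondrial protease (-2.87), COL4A2, a basement membrane collagen (-2.75), and KCNH2, a potassium channel (-2.59), with adjusted p-values of at most 0.000365 (limma). Of 7 other probe sets of YME1L1, only 2 passed in the same direction and 1 had the opposite sign.

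Over all, 4005 of 11108 probe sets changed with valproate (limma), 1914 up and 2091 down, for 2823 genes, and 593 of them by 2-fold or more, 299 up and 294 down. The median of the 18 hybridization spike probe sets was higher by 0.60 in valproate (SD 0.39 over 3 treated and 0.31 over 4 mock arrays), and 1061 of the 1914 rises were smaller than that and would be falls relative to the spikes, though none of the 8 largest. Treated and mock arrays stood apart for 42.5% of probe sets, where chance gives 5.71%. At 24 h alone 6186 probe sets passed limma's threshold, 2763 up and 3423 down, but with 1 treated array the spread came from the 3 mock arrays alone, which the labels call parallel replicates. At 8 h 377 probe sets lay beyond 2-fold, 172 up and 205 down, with no replicate check. Between 2 mock arrays of 24 h 1 probe set lay beyond 2-fold, against 847 to 902 for the 24 h and 1167 to 1221 for the 32 h valproate array. The log2 ratio of the 3′ to the 5′ probe set of ACTB was -0.084 ± 0.047 (SD, n = 4) in mock cells and 0.19 ± 0.11 (SD, n = 3) in valproate and that of GAPDH 0.17 ± 0.048 and 0.35 ± 0.026. Each was higher in 3 of 3 treated arrays, by 0.27 and 0.18, with an exact permutation p of 0.0571 (adjusted 0.0571), the smallest that 3 against 4 arrays allow, and of 0.0286 if counted by absolute size. The 2 definitions lie on either side of 0.05, and the design cannot settle this.

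**Figure D4:**
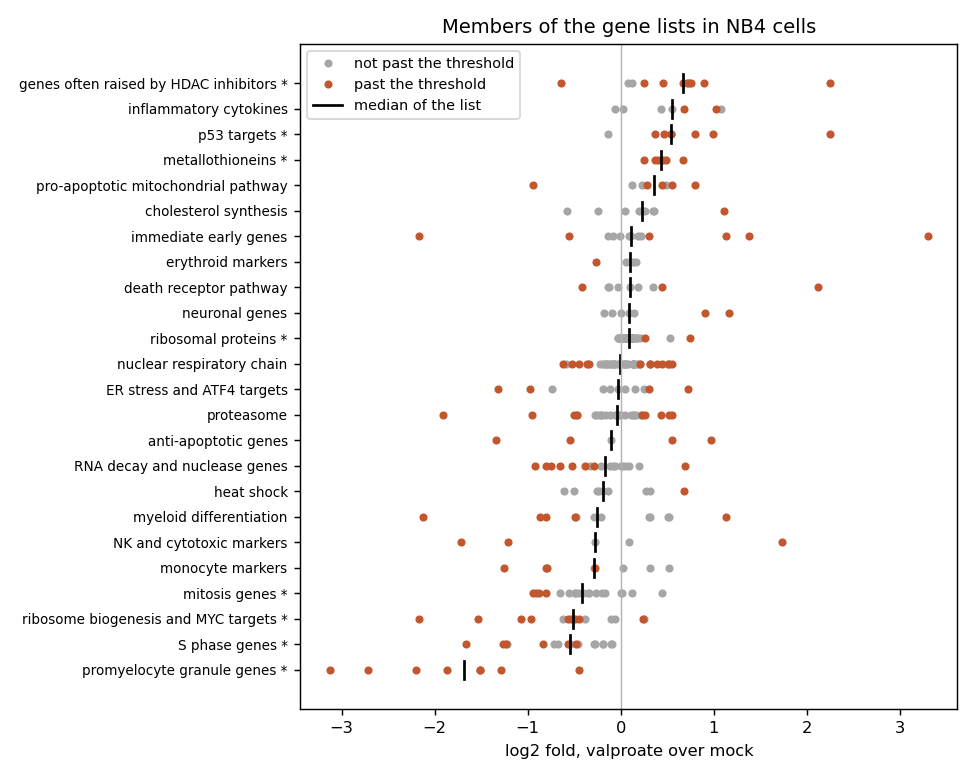
Log2 fold of valproate over mock (horizontal axis) for every tested member of 24 gene lists, 1 point per gene, coloured by whether it passed limma's threshold, with a bar at each list's median. Asterisks mark the 8 lists that passed camera with a preset correlation, none of which passed with an estimated one; the granule genes lie lowest, at a median of -1.69.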

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

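The tests of the donors, the scaling, breakage, the 28S probe set and the array splits were chosen as tests of an explanation after the results were seen.

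In 14 of 89 groups of the 4 mock NB4 arrays, 1 array lay far from the others by Dixon's ratio (limit 0.829), where chance gives about 1 in 20. In 12 of the 14 it was the 8 h array, which also differs in time from the other 3. The ratios were 0.972 for SPP1, 0.943 for RGS2, 0.848 for MOK, 0.976 for MCM7, 0.864 for CDKN1A, 0.856 for GLRX, 0.968 for SAT1, 0.939 for CYBB, 0.884 for JUN, 0.888 for PSMC4, 0.872 for NKG7 and 0.972 for HERPUD1. For NFE2 (0.866) and NDUFC1 (0.829) it was replicate 2 of 24 h.

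The effect of valproate at 24 h and at 8 h passed a test of difference for 2220 of 11108 probe sets (limma interaction term), a count that takes the spread of 1 group for all. Of the 4 groups in it 3 are single arrays and the spread is that of the 3 mock arrays of 24 h alone, so a difference in time cannot be separated from one between single arrays. Among the genes with the largest changes, the log2 effect at 24 h minus that at 8 h was 4.50 for SPP1, 2.63 for ICAM1, 2.50 for IER3, 1.70 for TSPAN13, 1.58 for CRISPLD2, 1.49 for TSC22D1, 1.36 for RGS2 and 1.22 for FUCA1. It was -3.45 for MPO, -3.10 for PRTN3, -1.88 for YME1L1, -1.79 for MOK, -1.04 for KCNH2, -0.75 for NFE2, -0.67 for COL4A2 and -0.54 for CEBPD, and these too are differences between single arrays. These genes were named for large changes over all times and do not show the usual course. Among the probe sets that passed, others had smaller effects at 24 h than at 8 h or effects of opposite sign.

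Median log2 intensities of the 9 hybridization spike probe sets were higher than at 0 ng by 0.46 at 25 ng, 1.09 at 50 ng and 1.39 at 100 ng of extract.

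The probe sets that changed at 100 ng of extract were weighed against the change of donors, the scaling and breakage of the RNA. Of the 544, 87.3% had already moved in their direction from 25 to 50 ng, samples the labels give to 1 donor. The share was 73.3% on the A arrays and 87.3% on the B arrays. This argues against the donors as the whole cause. Among 1606 probe sets picked for large p-values at 100 ng (limma) the share was 53.5%. Their direction is mostly noise, so a nearly even share was fixed in advance and adds no support. Scaling stays open for the direction of the changes: relative to the hybridization spikes 48.9% of the 544 kept their sign, the falls, and the labels do not give the amount of spike. Breakage by nucleases remains as a candidate explanation, since 72.1% of the genes that followed the degradation factor moved the same way in thawed cells, against 48% after valproate. The share of the 100 ng step that the donors add stays open, because no sample has 100 ng and the donor of the other amounts.

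A control probe set for the middle of 28S ribosomal RNA, which no comparison uses, was at 903 ± 49 (SD, n = 4) in mock NB4 cells and at 1195, 7912 and 19350 after 8, 24 and 32 h of valproate, 1 array each. Brighter arrays are argued against by the hybridization spikes, whose median log2 change at 32 h was 0.82 beside 4.42 for this probe set, and more ribosomal RNA of every part by a median of 0.42 over the other 11 ribosomal probe sets (-0.19 to 2.81, the highest being the 5′ probe set of the same 28S design). Breakage as by the extract is argued against as the whole rise by a change of 0.65 for the same probe set at 100 ng. The ACTB ratio moved by 2.01 there, against 0.27 after valproate. That change comes from blood cell RNA on another array design with other scaling, so its size compares only roughly with 4.42. The probe set did rise with extract, by 0.036 at 25 ng and 0.42 at 50 ng, so a part of breakage is not excluded. A ribosomal RNA change that grows with time in valproate may remain (log2 difference of 4.02 between 32 and 8 h), but with 1 array per time it cannot be told apart from differences between single arrays.

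The probe sets changed by valproate were weighed against other groupings, breakage and scaling. Of the 35 splits of the 7 arrays into 3 and 4, 1 gave as many changed probe sets, the real one with 4005, and the highest other gave 0. Every other split mixes treated and mock arrays, so the difference between them adds to its spread. The splits therefore say nothing on the cause. They argue against chance only if the 7 arrays are independent, and the labels call the 3 mock arrays of 24 h parallel replicates. Breakage like that by extract as the main source is argued against, but weakly, by r = -0.00905 across genes between the degradation slope and the valproate fold. The thaw fold gave 0.218, also across array designs, but from blood cells like the extract RNA, not NB4 cells. Genes were matched across designs, and 2 probe sets of one gene correlated at only 0.185 even at 100 ng. A low correlation therefore has limited power to show breakage. A smaller part of breakage cannot be excluded so, because a large response to another cause would hide it. The 3′ to 5′ ratios of ACTB and GAPDH were higher in valproate by 0.27 and 0.18. Scaling stays open for the smaller rises, since relative to the hybridization spikes 73.5% of the changed probe sets kept their sign. A response to valproate is one hypothesis that remains.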

How the results depend on the processing

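The list tests without the 8 h arrays and with the letters as a block were chosen after the results were seen, and the other alternatives before. Over 17 main results and 156 alternatives, 116 kept their direction and side of the threshold or, for counts, stayed within 1.5 times, and 40 did not. Correlations across genes counted as moved only beyond 0.1, a limit set for this purpose; they ranged from 0.155 to 0.221 for the thawed cells and from -0.0249 to -0.0115 for valproate. Those of the ACTB and GAPDH ratios with the degradation factor stayed between 0.948 and 0.992 without any 1 array.

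For 100 ng the 544 changed probe sets became 157 with only the 2 groups compared in the fit, 2289 with the letters as a block, 323 among single-transcript probe sets and 33 to 351 without 1 array. For 50 ng the 6 became 0 with no filter, 0 with single-transcript probe sets, 0 with only the 2 groups compared, 554 with the replicate block and 0 to 1 without 1 array. For 25 ng the 0 (limma, 428 at an unadjusted p below 0.05) became 23 with the block and 0 to 2 without 1 array, the 2 being without 25 ng A. For the regression the 705 became 1769 with the block, 5 without the 100 ng arrays and 224 to 756 without 1 array. In thawed cells the 0 (limma, 669 at an unadjusted p below 0.05) became 161 with the spread shared with all arrays of the platform and 1016 with h and n as a block, and stayed at 0 without any 1 array. Deviations of h and n correlated between the 2 times (r = 0.759), within the range of the extract amounts (0.618 to 0.799). Arrays of a letter were closer (r = 0.9712 for h and 0.96 for n) than arrays of a time (0.9447 at 0 min and 0.9235 at 5 min). These values point to pairing by letter, as for A and B. With 1 pair of times and no statement in the labels, the block of h and n was kept as an alternative. In that block the lists of NK and cytotoxic, monocyte, platelet, B cell and T cell markers passed camera as down (adjusted p = 1.74e-05, 9.41e-06, 0.0078, 0.00916 and 0.0436), and the proteasome did not (0.0556). With an estimated correlation the 5 lists had an adjusted p = 0.873 each in that block. The block of A and B changed no other call than those given with the 100 ng lists.

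For valproate the 4005 became 2396 with the stricter intensity filter and 1793 among single-transcript probe sets. At 24 h the 6186 became 3800 and 2741, and at 8 h the 377 became 174 and 183. Fewer probe sets were tested there, and fewer arrays were fitted when 1 array or the 100 ng arrays were left out; for the other changes the cause was not tested. With an estimated correlation 0 of 2 lists remained past the threshold in thawed cells and 0 of 8 after valproate. All lists then had camera adjusted p-values of 0.856 to 0.922 in thawed cells and 0.624 to 0.871 after valproate. These ranges include lists whose estimated correlation was below the preset one. The losses therefore do not show that the members of a list vary together. Without the 8 h arrays 8 lists passed, with the inflammatory cytokines entering (adjusted p = 0.00448) and the mitosis genes leaving (0.0593).

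For 134 named genes and 1951 alternatives, 1715 kept their call, 216 lost it, 19 gained one and 1 reversed. MNDA in thawed cells, at -0.62 and not passing, ranged from -1.32 without the 5 min h array to 0.10 (0.101) without the 5 min n array. Of 45 genes that lost a call under some alternative, 23 did so other than by leaving out an array. The spread between 2 arrays per group limits the thawed cells, where 25.8% of simulated 2-fold changes were recovered.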

Other observations

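The test of probe sets of the same gene was chosen after the results were seen, and the lists were fixed before.

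Other gene lists in valproate-treated NB4 cells did not pass camera. Of 45 respiratory chain genes 8 rose and 5 fell (7 and 5 adjusted over the list alone; adjusted p = 0.702), including NDUFB3 (0.55) and NDUFC1 (-0.62). Of 28 proteasome genes 5 rose and 4 fell, with PSMB10 (-1.91) and PSMB8 (-0.96) lower and PSMC4 (0.55) and PSMD2 (0.52) higher (adjusted p = 0.702). Of 14 immediate early genes 4 rose and 2 fell, among them IER3, EGR1 (1.37) and JUN (1.13) against MYC (adjusted p = 0.509). Of 7 inflammatory cytokine genes IL1B (1.02) and TNFAIP3 (0.68) rose (4 adjusted over the list alone; adjusted p = 0.113). Of 12 myeloid differentiation genes 1 rose, ITGAM (1.13), and 4 fell, CYBB (-2.13), CSF3R (-0.87) and CYBA (-0.81) among them (3 and 6 adjusted over the list alone; adjusted p = 0.507). Of 8 monocyte markers 4 fell, including MNDA (-1.25), CTSS (-0.80) and TYROBP (-0.80; 1 rose and 5 fell adjusted over the list alone; adjusted p = 0.169). Of 5 NK and cytotoxic markers PRF1 (1.73) rose and CST7 (-1.72) and NKG7 (-1.21) fell (adjusted p = 0.555).

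Of 18 RNA decay and nuclease genes 7 fell and 1 rose, with ENDOG (-0.92), EXOSC8 (-0.80) and EXOSC7 (-0.75) lower and DCP2 (0.69) higher (adjusted p = 0.0786). Of 11 ER stress genes 2 rose and 2 fell (2 and 3 adjusted over the list alone), with TRIB3 (-1.32) and XBP1 (-0.98) lower and HERPUD1 (0.72) higher (adjusted p = 0.678). BAG3 (0.68) rose among 9 heat shock genes (adjusted p = 0.702), LSS (1.11) among 8 of cholesterol synthesis (0.381), and ENO2 (1.16) and UCHL1 (0.90) among 7 neuronal genes (0.507). Of 5 erythroid markers 1 fell (0 adjusted over the list alone; 0.735). Too few members were tested for T cell (4), B cell (3), granulocyte (3), platelet (4) and histone genes (4). Calls lost without 1 array were those of PRF1 without any 1 mock array (up to 0.0921), ITGAM without the mock 8 h array (up to 0.0783), and PRF1, ITGAM, NKG7 (0.0543), TNFAIP3 (0.071) and EXOSC7 (0.0575) without the 24 h valproate array. That of PSMC4 was lost without any array but the mock 8 h and the 8 h valproate ones (up to 0.086), that of NDUFC1 without the mock 24 h replicate 2 or the 24 h valproate array (up to 0.0782), and that of CYBA without the mock 24 h replicate 3, the mock 8 h or the 24 h valproate array (up to 0.0604).

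At 100 ng of extract, 1 gene rose in the mitosis, histone, deacetylase inhibitor and myeloid differentiation lists each, and 1 fell in the histone and deacetylase inhibitor lists each. With the letters as a block 3 deacetylase inhibitor genes rose and 1 fell, 2 myeloid differentiation genes rose and 1 fell, 2 ribosome biogenesis genes rose and 1 fell, and 1 RNA decay and 1 cytokine gene rose and 2 of each fell. In it 2 metallothioneins rose, 2 anti-apoptotic genes fell, and 1 gene each rose in the mitosis, S phase, granule, ER stress and neuronal lists and fell in the mitosis, mitochondrial pathway, cholesterol and neuronal lists. The p53 (3) and cholesterol (4) lists were too small to test. Median, mean and test of a list differed in sign for 4 lists at 100 ng (heat shock, mitosis, metallothioneins and neuronal), 5 in thawed cells (ribosomal proteins, erythroid, deacetylase inhibitor, metallothioneins and RNA decay) and 1 after valproate (respiratory chain).

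Folds of different probe sets of the same gene correlated less with extract than with valproate. Over 703 genes the 100 ng folds of 2 probe sets correlated at r = 0.185, and 54.3% had the same sign, against r = 0.799 and 80.2% over 2013 genes for valproate and r = 0.388 and 63.5% over 1954 genes in thawed cells. The extract arrays are of another design than the thawed and NB4 arrays. Fewer probe sets changed by 2-fold or more at 100 ng than with valproate (30 against 593). Array design and size of the folds cannot be told apart from the treatment in this comparison. Where both probe sets had changed, the signs were the same for 9 of 9 genes at 100 ng and 524 of 526 after valproate. The 100 ng folds of the brighter probe set of each gene correlated at r = 0.80 between the letters A and B. This argues against noise of the brighter probe sets as the cause at 100 ng. In thawed cells the same value was 0.45 between h and n, little above the 0.388 of 2 probe sets, so the thawed result may reflect noise. For valproate it was 0.875 between 2 pairs of treated and mock arrays. The same was not computed for the dimmer probe sets, so their noise is not excluded. A candidate explanation is that breakage changes the signal by the part of the transcript a probe set reads, which was not tested, since the positions of the probes were not used here. Genes are not independent replicates here.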
